A study of Oryza sativa with 12 samples.

How the data were processed

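RNA was measured in rice (Oryza sativa) from shoot and root of the wild-type cultivar Nipponbare (WT) and of the mutant line osspt5-1#12. The 4 groups held 3 libraries each, 12 libraries in all. Per the labels' protocols, plants grew in a chamber with 15 h of light at 28 °C and 9 h of darkness at 24 °C, at 70% relative humidity. Libraries were made from 2 µg of total RNA with the NEBNext Ultra RNA kit, per the labels' protocols. That kit does not mark strand, so reads from a gene and from an overlapping antisense gene cannot be told apart. Genes with near-identical copies are uncertain as well. The labels number the replicates but do not say whether they came from separate plants, so p-values measure the spread between these libraries, which may be partly technical.

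The deposited values are FPKM (fragments per kilobase of gene length, scaled to library depth) per row, 1 file per library, per the file headers. The submitters' processing notes name HISAT2 2.1.0, Bowtie2 2.2.3, HTSeq 0.6.0 and the genome build IRGSP-1.0, without their role or order. The annotation release and the filters are not given in the sources used here. The shoot files held 35395 rows and the root files 34948, with no row at 0 in all libraries of its tissue, and a row missing from one tissue was set to 0 there. Of the 38034 identifiers, 31003 were rice locus identifiers, 6882 began with EPlOSAG (EPl rows below) and 149 were of other kinds. The chromosome of a locus was read from its identifier, and no coordinates were used.

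The files do not pair identifiers with gene names. The reference table used for names (assembly ASM3414082v1, 39387 entries) matched 1 of the 38034 identifiers. OsSPT5-1 itself and the gene lists fixed before the data were examined were therefore not analysed here, and the genotype labels were not checked on the targeted gene. The rule for named genes then allows 2 identifiers that rose and 2 that fell per comparison. They are those with the largest log2 fold changes among rows with adjusted p under 0.05, a mean of at least 1 FPKM in the tissue and no overlap between the mutant and WT libraries. Gene groups were instead defined from the libraries, after the data were examined: 462 shoot-preferred and 278 root-preferred locus rows. These differed between root and shoot by at least 3 on the log2 scale (8-fold) in the mean of both genotypes. That mean is unrelated to the difference between mutant and WT within a tissue only if both genotypes spread equally. WT shoot libraries spread more than mutant shoot libraries, which can pull the shoot-preferred median in shoot down.

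Depth was recovered from the deposited FPKM values, because the values of a row are whole multiples of what 1 read is worth. With a tolerance of 0.002 reads, 100% of rows came out as whole reads, and 98.2% gave a length within 0.05 bases of a whole number. On simulated reads, 99.87% of the 3870 rows above 0 in 5 or more libraries were recovered exactly. Rows read in fewer libraries were not scored. The smallest number of reads that fits was taken, so a row read in 1 library always comes out as 1 read. The share of whole reads is therefore no check on such sparse rows, whose reads and lengths are uncertain. Recovered totals ran from 10118071 to 15749857 reads per library. At these depths 3 reads of a row 1 kb long correspond to between 0.19 and 0.296 FPKM. A fold change against a group with no reads was computed against a floor of 3 reads over that group and is a lower bound, which covers counting error only.

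Tests were made with limma 3.58.1 in R 4.3.3 (limma-trend, Benjamini-Hochberg adjustment, adjusted p under 0.05) on log2(FPKM + 1). All 12 libraries entered a single fit with a mean per group and an estimate of the spread of each row that all groups share. The 25337 rows at 1 FPKM or more in at least 3 libraries were tested. A log2 fold change is thus on the log2(FPKM + 1) scale and understates the change of low rows. The design fixed before the data were examined named a count test first and this test for FPKM, and the latter applied. Contrasts were mutant minus WT in shoot, the same in root, the difference between these effects, and WT root minus WT shoot. Groups of genes were tested with camera at a preset correlation of 0.01, two-sided, adjusted over 15 sets per contrast (both preferred groups, 12 chromosomes and the EPl rows). For the difference between tissues the adjustment was first made over the 2 preferred groups alone and was extended to the 15 sets after those values were seen. They were tested again with camera at an estimated correlation, and with fry, which asks whether a group moves one way without comparing it with other genes. The position of a group's median was also taken among 10000 random lists of the same size and the same mean level over all 12 libraries.

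The procedure was tested on simulated data. For shoot, with 24240 genes, 61 of 100 genes changed 4-fold and 13 of 100 changed 2-fold were recovered, and 17 unchanged genes were called. In root, where no gene was changed, 6 were called. Small changes were therefore mostly missed in this simulation of 3 libraries per group. Among its shoot calls, the share of unchanged genes was above the threshold set on adjusted p. Real calls may also hold more false ones than that threshold implies, but the simulation does not decide this. It changed only 200 genes, while 2406 rows were called in the real shoot data. It also gave each gene a spread drawn without regard to its level, and added counting noise to spreads that already held it. The shares recovered and falsely called in the real data may therefore differ. The alternatives tried were another pseudocount (0.1), other filters, median-ratio factors, quantile normalization, limma-voom on recovered reads, a replicate block, fits of the compared groups alone, a fold threshold, locus rows alone, and leaving out each library. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.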

Results

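The series asks how depletion of OsSPT5-1 changes gene expression in the shoot and root of rice during vegetative growth. SPT5 proteins are transcription elongation factors that travel with RNA polymerase II. FPKM values of the mutant line osspt5-1#12 and of WT Nipponbare were compared in 4 groups of 3 libraries. Recovered depth was 14937501 to 15127186 reads per library in WT shoot, 10612862 to 15749857 in mutant shoot, 10118071 to 13524346 in WT root and 13497181 to 15522895 in mutant root. The level of OsSPT5-1 was not analysed here.

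Replicate libraries differed in how closely they matched. Pearson's r of log2 values across genes was 0.961 to 0.965 between WT root libraries and 0.962 to 0.971 between mutant shoot libraries. It was 0.908 to 0.951 between WT shoot libraries and 0.877 to 0.92 between mutant root libraries. A pair of short rows, EPlOSAG00000023740 and EPlOSAG00000023741, chosen after their values were seen, took 1.88% and 2.78% of reads in mutant shoot libraries 1 and 3 and 1.62% in WT root library 1. They took at most 0.273% in each of the other libraries. Mutant shoot libraries 1 and 3 and WT root library 1 also had the lowest recovered totals of all libraries (12208108, 10612862 and 10118071 reads). In shoot this difference lay in mutant libraries only, so it cannot be fully separated from genotype there.

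In WT plants, root and shoot expressed different genes. Of 25337 rows tested, 8702 differed between WT root and WT shoot (limma, adjusted p under 0.05), 4513 higher in root and 4189 higher in shoot. With median-ratio factors the split turned to 3951 higher in root and 4692 higher in shoot. The majority also turned with quantile normalization, for changes of at least 2-fold, and without WT shoot library 2 (3289 higher in root, 3672 in shoot) or any WT root library (3233 to 3390 and 3418 to 3621). At least 2-fold differences were found for 6340 rows. This difference gives the mutant effects a scale: 34.4% of rows differed between the tissues, against 9.5% between mutant and WT in shoot and 7% in root.

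In shoot, 2406 rows changed in the mutant, 1217 higher and 1189 lower than in WT (limma, adjusted p under 0.05). Locus rows made up 2160 of them, and 1733 changed at least 2-fold, 771 higher and 962 lower. On the log2(FPKM + 1) scale, the locus with the largest fall was Os08g0167800 on chromosome 8. It had 756.4 ± 115 FPKM in WT shoot (SD, n = 3) and 0.186 ± 0.125 in mutant shoot. That is 4068-fold lower, against 12 reads in the mutant, and 6622-fold without mutant shoot library 2, with a log2 fold change of −9.31 (SE 0.182, limma adjusted p = 8.19e-10). Os08g0139700, on the same chromosome, fell from 286 ± 41 to 0.561 ± 0.208 FPKM, 510.2-fold (log2 fold change −7.52, SE 0.185, limma adjusted p = 3.09e-09). Both loci had under 0.08 FPKM on average in roots of either genotype.

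On the log scale used for the tests, the called rows with the largest rises in mutant shoot were short EPl rows without a read in WT. The order differs for folds of plain FPKM. Os03g0115800, with 0 reads in WT shoot, was at least 1089-fold higher in mutant shoot, a larger lower bound than those of the EPl rows given here. EPlOSAG00000020468 (55 bases) had 0 reads in all 6 WT libraries and 239.2 ± 10.1 FPKM in mutant shoot (SD, n = 3), from 510 reads. This was at least 197.7-fold higher (limma adjusted p = 9.16e-09). EPlOSAG00000020549 (44 bases) likewise had 0 reads in WT and 201.4 ± 4.87 FPKM in mutant shoot, at least 133.4-fold higher (limma adjusted p = 9.16e-09).

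The share of higher calls in shoot moved with the scaling. With median-ratio factors 793 rows were higher and 1563 lower, 33.7% higher against 50.6% with the deposited scaling. The median log2 fold change of all rows was 0.13 as deposited and −0.01 with those factors, so small rises in shoot are relative to this shift. The balance also moved with single libraries: without WT shoot library 1, 1610 rows were higher and 1019 lower, and without a mutant shoot library 38% to 42.1% were higher. Leaving out any shoot library except WT library 1 lowered the count to between 1067 and 1266, and fitting the shoot groups alone raised it to 3682.

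Genes preferred by shoot had a lower median in mutant shoot than in WT shoot, although most of them did not pass the test. Of 462 shoot-preferred genes, 108 fell, 10 rose and 344 did not pass the test. Their median log2 fold change was −0.35 (1.28-fold lower), against 0.15 for random lists of the same mean level over all 12 libraries. Camera called the group (adjusted p = 8.01e-14) but not with an estimated correlation (adjusted p = 0.834 with an estimated correlation), and fry's adjusted p was 0.015. The medians of the 3 mutant shoot libraries were −0.35, −0.19 and −0.51 relative to the WT mean, and those of WT were −0.18, 0.3 and −0.15. Without WT shoot library 2, which stood above the others, the median was −0.23, and without mutant shoot library 3 it was −0.25 (camera adjusted p = 5.03e-10 and 5.5e-12). Of 278 root-preferred genes, 16 rose in mutant shoot and 0 fell, with a median of 0.08. Camera did not call them (adjusted p = 0.921), and the median was −0.02 under quantile normalization.

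In root, 1774 rows changed in the mutant, 667 higher and 1107 lower (limma, adjusted p under 0.05). Locus rows were 1591 of these, and 1277 rows changed at least 2-fold, 321 higher and 956 lower. Os03g0115800 on chromosome 3 rose from 0.121 ± 0.209 FPKM in WT root to 167 ± 26.2 in mutant root (SD, n = 3), 1385-fold. The WT value rests on 7 reads in library 2, with 0 in the other two, so the size of this fold depends on that library. Its log2 fold change was 7.23 (SE 0.182, limma adjusted p = 1.24e-08). EPlOSAG00000020468 had 0 reads in WT root and 211.9 ± 89.2 FPKM in mutant root, at least 143.1-fold higher (limma adjusted p = 5.73e-08).

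Os10g0334500 on chromosome 10 fell from 85.4 ± 37.3 FPKM in WT root to 0 reads in the 3 mutant root libraries, at least 762.6-fold lower. Its log2 fold change was −6.32 (SE 0.569, limma adjusted p = 0.000193). EPlOSAG00000023827 had 83 ± 38.2 FPKM in WT root and 0 in mutant root (limma adjusted p = 0.0419). Its recovered length of 15 bases is doubtful, so its reads are uncertain and no fold is given. This call was lost without any 1 WT root library, without mutant root library 2 or 3 and with no filter on low values, with adjusted p between 0.00262 and 0.144 over the settings tried. The count of root calls depended on the mutant root libraries, which differed most from each other: without mutant library 1 it was 4553, and the majority turned, with 2518 higher and 2035 lower. Leaving out a WT root library gave 607 to 772, and fitting the root groups alone gave 419, with 82 higher and 337 lower. The single fit shares its spread with groups whose libraries mostly matched more closely, so its p-values for root may be too small.

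**Figure D1:**
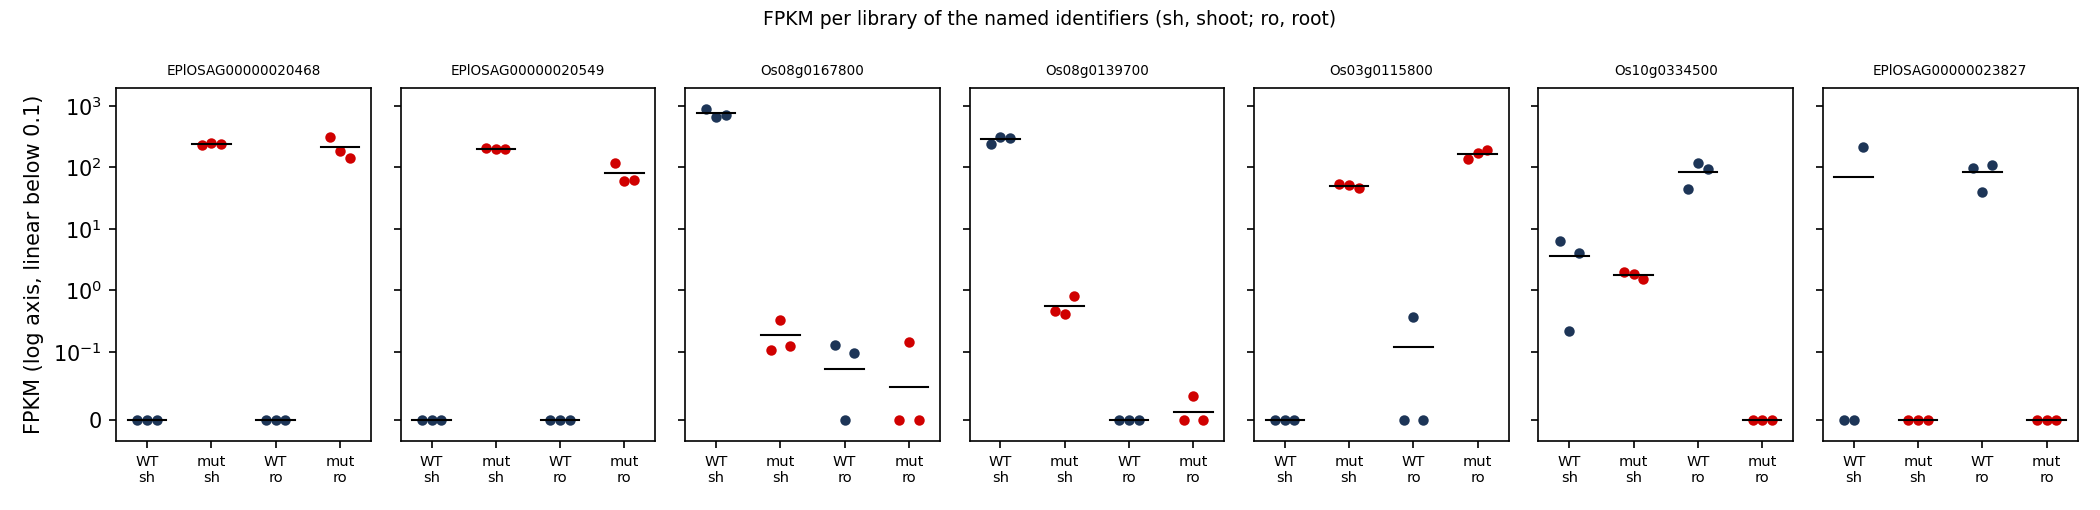
FPKM of the 7 named identifiers in each library, on a log axis that is linear below 0.1; points are libraries (blue WT, red mutant), bars are means of 3 libraries. Os08g0167800 and Os08g0139700 lie above 200 FPKM in WT shoot and below 1 in mutant shoot, and both EPl rows that rose are at 0 in every WT library.

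Genes preferred by root had a lower median in mutant root than in WT root, although most of them did not pass the test. Of 278 root-preferred genes, 63 fell, 8 rose and 207 did not pass the test, with a median log2 fold change of −0.77 (1.7-fold lower). Camera called the group (adjusted p = 5.3e-12) but not with an estimated correlation (adjusted p = 0.117 with an estimated correlation), and fry's adjusted p was 0.00338. The library medians were −0.32, −0.95 and −0.8 in mutant root and −0.01, 0 and 0.04 in WT root. Of 462 shoot-preferred genes, 29 fell and 2 rose in mutant root, with a median of −0.17 and a camera adjusted p of 2.94e-05 (adjusted p = 0.995 with an estimated correlation). Here fry did not call the group (adjusted p = 0.38). The camera call ended without mutant root library 2, when the median was −0.03 (camera adjusted p = 0.312), and the median was −0.31 without mutant root library 3.

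**Figure D2:**
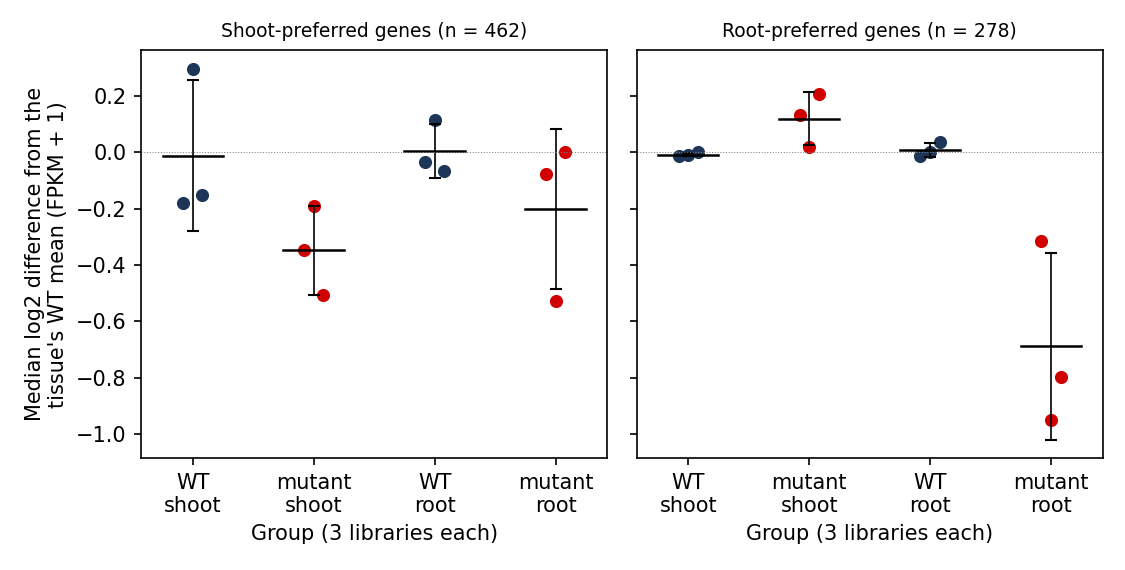
Median log2 difference from the WT mean of the same tissue, on the log2(FPKM + 1) scale, over 462 shoot-preferred and 278 root-preferred genes; each point is a library, long bars are means and error bars are SD (n = 3). The root-preferred genes lie at −0.32, −0.95 and −0.8 in mutant root, and the shoot-preferred genes at −0.35, −0.19 and −0.51 in mutant shoot.

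The mutant effects in shoot and root fell partly on shared genes. Of the rows tested, 378 were called in both tissues in the same direction, 157 higher and 221 lower, and 49 were called in opposite directions. Independent lists would share 32 higher and 52 lower rows. The odds ratios were 6.86 (95% interval 5.64 to 8.3) and 5.99 (5.08 to 7.05) by Fisher's exact test across genes, which are not independent replicates. Spearman's rho of the log2 fold changes across genes was 0.334. With median-ratio factors 107 shared rows were higher and 298 lower. The shared count was 194 to 226 when WT shoot library 3, any mutant shoot library or any WT root library was left out, 626 without mutant root library 1 and 630 without mutant root library 3. The shoot and root comparisons used different WT libraries but the same estimate of the spread of each row. Rows with a small spread could thus be called more easily in both tissues, which the numbers for independent lists leave out. With the groups of each tissue fitted alone, 138 rows were shared, 45 higher and 93 lower. Os03g0115800 was among the rows higher in both: it had 0 reads in WT shoot and 50.6 ± 3.54 FPKM in mutant shoot, at least 1089-fold higher (limma adjusted p = 1.47e-08). EPlOSAG00000020549 was also higher in root, at 81.2 ± 33.6 FPKM against 0 reads in WT, at least 43.87-fold (limma adjusted p = 1.36e-07).

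**Figure D3:**
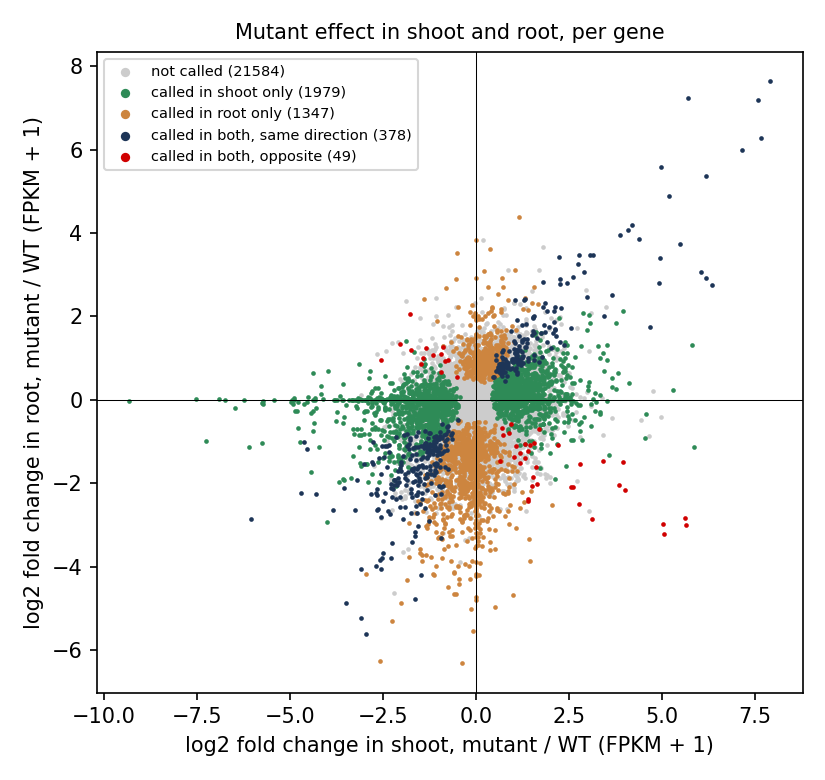
Log2 fold change of mutant over WT in shoot (x axis) and root (y axis) on the log2(FPKM + 1) scale; each point is 1 of 25337 tested rows, coloured by where it was called. The 378 rows called in both tissues in the same direction lie at the upper right (157) and lower left (221).

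The mutant effect itself differed between root and shoot for 893 rows, with 392 more positive and 501 more negative in root (limma interaction contrast, adjusted p under 0.05). The majority was not stable: the split was 524 and 418 under quantile normalization, and it also turned without any 1 mutant shoot library (223 to 247 against 205 to 218), any 1 WT root library (230 to 254 against 210 to 230) or mutant root library 2 (419 and 415). The count was 522 with a pseudocount of 0.1 and 366 with limma-voom. It was 428 to 484 when WT shoot library 2 or 3, any mutant shoot library or any WT root library was left out, and 1925 without mutant root library 1. The falls of Os08g0167800 and Os08g0139700 were larger in shoot (limma interaction adjusted p = 3.53e-08 and 1.23e-07), and that of Os10g0334500 was larger in root (adjusted p = 0.00304). Os10g0334500 had only 3.59 ± 3.15 FPKM in WT shoot, so it had little room to fall there. Among root-preferred genes, the effect was more negative in root for 29 and more positive for 2, with a median difference of −1.17 (camera adjusted p = 7.31e-11; adjusted p = 0.151 with an estimated correlation). These genes had median levels of only 0.76 to 1.17 on the log2(FPKM + 1) scale in shoot libraries, so they had little room to fall there.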

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

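The tests of splits and of explanations in this part were chosen after the results they concern were seen. Groups of 3 libraries are too small for a test of single outlying libraries.

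The mutant effect differed between root and shoot, by the interaction test, for 893 rows. Among 100 splits of the libraries within tissues, 3 gave as many rows, the real one included, and the highest of the others gave 4297. That split kept the shoot genotypes and exchanged the genotype names of all root libraries, so that it added the effects of both tissues instead of subtracting them. The other large ones kept the shoot genotypes too and gave 996, 773 and 762 rows. The libraries are thus structured by the shoot effect. A split that breaks both tissues removes both effects and one that alters root alone reaches counts like the real one, so these splits do not decide on chance as the origin of the 893 rows.

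Of the named identifiers, 5 had an effect that differed between tissues. Root minus shoot, the difference in log2 fold change was 9.28 for Os08g0167800, 7.54 for Os08g0139700, −5.96 for Os10g0334500, 1.54 for Os03g0115800 and −1.37 for EPlOSAG00000020549 (limma adjusted p = 3.53e-08, 1.23e-07, 0.00304, 0.0094 and 0.0457). The shoot loci had almost no reads in root of either genotype, so they had no level there from which to fall. Likewise, Os10g0334500 had only 3.59 ± 3.15 FPKM in WT shoot and little room to fall in shoot. The shoot-preferred genes had a median difference of 0.025, while 59 members had a more positive effect in root and 10 a more negative one (camera adjusted p = 0.00148; adjusted p = 0.942 with an estimated correlation). These genes had median levels of only 0.951 to 1.86 on the log2(FPKM + 1) scale in root libraries. They had little room to fall there, so a more positive effect in root can restate a fall in shoot.

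The root-preferred genes had a median difference of −1.17 between tissues, which mostly restates their fall in root, since their level in shoot was low. Each tissue's own preferred genes had lower medians in the mutant, −0.3518 in shoot and −0.7694 in root, but 344 of 462 and 207 of 278 did not pass. The camera calls of both groups were lost with an estimated correlation, as given below. The lowest of 10000 random lists of the same mean level over all 12 libraries had medians of 0.04 and −0.04. The level within the tissue itself was not matched, so these lists do not decide on level and log scale. Material of the other tissue is argued against: it would need 21.6% root RNA in mutant shoot and 41.3% shoot RNA in mutant root. The 10th percentile of the other tissue's abundant preferred genes reached only 0.352% and 0.0855% of their WT level there, in the highest mutant library. Under median-ratio factors and quantile normalization the medians closest to 0 were −0.3668 and −0.7951, so scaling does not remove the pattern. The shoot-preferred genes had a median of −0.17 in mutant root, but of −0.03 without mutant root library 2. The genotype itself, a difference in developmental stage and one in organ composition stay open, and none of them was tested. With an estimated correlation the camera calls within each tissue and for the difference between tissues were lost (adjusted p = 0.834, 0.117 and 0.151 with an estimated correlation). The last was kept when adjusted over the 2 preferred groups alone, as first done (adjusted p = 0.0202 with an estimated correlation).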

How the results depend on the processing

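Quantile normalization, locus rows alone and all settings for the tissue-preferred groups were chosen after the data were examined. With a replicate block the counts were 1189 in shoot, 566 in root, 233 for the difference between tissues, 3848 for WT root against shoot (1662 higher in root, 2186 in shoot) and 141 shared, and EPlOSAG00000023827 lost its call (limma adjusted p = 0.0835). Same-numbered libraries did not deviate together across genotypes (correlations of −0.116, 0.141 and −0.0493 in shoot and −0.274, −0.111 and −0.176 in root), and shoot and root libraries of 1 genotype did not all do so (0.112, 0.032 and 0.185 in WT, 0.0975, −0.121 and 0.137 in the mutant). The check thus does not show that the numbers pair the libraries, and whether shoot and root share plants is not known from the labels. Fitting only the compared groups gave 3682 in shoot, 419 in root and 138 shared. Such a fit has fewer libraries and takes the spread from the compared groups alone. The single fit shares its spread over groups whose libraries matched unequally, with mutant root matching least, so its counts depend on that sharing. The difference between tissues gave 522 rows with a pseudocount of 0.1 and 366 with limma-voom, and the cause was not tested. Leaving out each library gave 1067 to 2629 in shoot, 607 to 4553 in root, 428 to 1925 for the difference, 6757 to 7771 for WT root against shoot and 194 to 630 shared. Of the calls of mutant against WT, up to 1378 of 2406 in shoot and 1191 of 1774 in root were lost, up to 171 and 99 of them because they were no longer tested, and none still tested changed sign. Fewer libraries lowered most counts, but root gave 4553 without mutant library 1 and 2308 without mutant library 3. The medians ran from −0.459 to −0.226 (shoot-preferred, shoot), 0.0669 to 0.152 (root-preferred, shoot), −0.311 to −0.0347 (shoot-preferred, root) and −0.925 to −0.723 (root-preferred, root) without single libraries. Medians over 1.5 times away elsewhere were −0.541 with median-ratio factors (shoot-preferred, shoot), 0.043 with those factors, 0.286 with a pseudocount of 0.1 and 0.394 with limma-voom (root-preferred, shoot), and −0.324, −0.43 and, at a preference of 2, −0.0723 (shoot-preferred, root). Preference defined on 2 WT libraries of the tissue, with the fold taken from the third, gave own-tissue medians of −1.04 to −0.612 in shoot and −1.31 to −1.17 in root. That preference was set on WT alone, so genes high only in WT could enter and genes high only in the mutant could not. This choice favours falls, so these medians do not check the main ones. The root-preferred median in shoot turned to −0.0200 under quantile normalization, with no call under any setting. Of the single identifiers, 111 results under other settings kept direction and call, and 7 lost the call, all of EPlOSAG00000023827. These do not cover Os08g0167800 and Os08g0139700 without a WT shoot library, since both then missed the filter and were not tested. Their folds in shoot, WT over mutant, were then 3715 to 4294 and 483.1 to 551.7. The planned negative-binomial tests on counts and the trimmed-mean scaling were not run. Scaling by library size alone is what the deposited values already hold. Alternatives for the gene lists and for OsSPT5-1 were not run either.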

Other observations

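The test of windows of neighbouring loci was planned before its result was seen; the other tests here were chosen after the results they concern.

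Of 1320 loci with a mean of at least 100 FPKM in WT or mutant shoot, 120 fell and 56 rose, with 25 at least 10-fold lower and 4 at least 10-fold higher. Of 1531 such loci in root, 146 fell and 74 rose, with 13 at least 10-fold lower and 2 at least 10-fold higher. Among the 20766 loci below that level in shoot, 964 fell and 1020 rose, and among the 20555 in root, 823 fell and 546 rose. At least 10-fold changes there were 154 lower and 111 higher in shoot and 141 lower and 34 higher in root. Whether the share of falls differs with level was not tested, and with other scaling the balance of all shoot calls shifts to falls as well. Between 8.94% and 11.2% of loci on each of the 12 chromosomes were called in shoot and between 5.75% and 9.87% in root, a spread that was not tested. Camera, which tests a net direction, called no chromosome (lowest adjusted p = 0.921 and 0.406). Of 3198 EPl rows, 138 rose and 104 fell in shoot, and 47 rose and 135 fell in root (camera adjusted p = 0.921 and 0.0529).

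For counts over 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split was the 1 with as many rows in each case: 2406 against a highest other of 2 in shoot, 1774 against 6 in root, and 8702 against 2 for WT root and shoot. For the 378 shared rows, 1 of 100 splits within tissues gave as many, the real one, and the highest other gave 49. A split that breaks a tissue leaves almost no calls there, so these splits restate the calls per tissue and do not decide on chance as the origin of the sharing.

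In the mutant, 10 rows had at least 20 reads in each of the 6 libraries and at most 3 reads in each WT library, and 0 rows showed the reverse. They were 5 EPl rows of 44 to 125 bases, among them EPlOSAG00000020468 and EPlOSAG00000020549, and 5 loci. Of 100 splits, 1 gave as many such rows, the real one, and the highest other gave 1. The 5 loci lie on 5 chromosomes, which argues against a single linked segment. A different genome in the line stays open: 0 rows were read only in WT over both tissues, but within shoot 41 rows had at least 20 reads in each WT library of that tissue and at most 3 in each mutant library, against 24 rows the other way round. Within root these were 13 and 12 rows. Loss of OsSPT5-1 and another change in this line cannot be told apart, since the series holds 1 mutant line; several separate changes may also be present.

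The mutant root libraries spread widely. Lower depth is argued against, since the lowest mutant root total was 13497181 reads and the lowest of WT root 10118071. The 2 abundant EPl rows are argued against too, with at most 0.273% of reads in mutant root, below the 1.62% in WT root library 1. A single outlying library stays open: the best mutant root pair had r = 0.9198, below the worst WT root pair (0.961) but within the WT shoot range of 0.908 to 0.951, and that pair leaves out library 3. The root calls rose from 1774 to 4553 without library 1 instead, which leaves the pair with the lowest r (0.8769), so these values point at different libraries. A single outlying library cannot be told apart from a more variable growth of mutant roots, which is untested.

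If long genes needed the elongation factor most, their transcripts should be lower in the mutant. The length used was the one recovered from the FPKM values. Without coordinates, the length of the transcribed gene with introns was not known. Spearman's rho of recovered length and log2 fold change across 22086 loci was 0.0903 in shoot. All mutant libraries (0.0705 to 0.1) lay above the range of single WT libraries (−0.0243 to 0.0314). Loci with a long recovered length were thus not lower in mutant shoot, which does not decide on gene length with introns. In root, rho was −0.0812, within the WT range of −0.083 to 0.143. Single mutant libraries ran from −0.14 to −0.0131 there, partly below that range in the direction of the hypothesis, so root does not decide. Genes are not independent replicates.

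Linked segments of the genome would place shared calls side by side. Among 341 loci called in both tissues in the same direction, the densest window of 50 neighbouring loci held 6, on chromosome 8. Of 10000 shuffles, 2136 held as many and the highest held 9, so the windows argue against dense clusters of such genes.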
